A study of Oryza sativa with 8 samples.

How the data were processed

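Total RNA from roots and shoots of rice seedlings, of wild type and fit-1, with and without iron for 5 days, was labelled with Cy3 and hybridised to 8 one-colour Agilent rice arrays. Per the labels, seedlings were germinated for 4 days, precultured with iron for 5 days at 28 °C by day and 20 °C at night with 14 h of light, and each array carried a pool of 3 biological replicates. Each of the 8 groups is 1 array, so no spread between plants could be estimated within a group.

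The authors scanned the arrays and extracted signals with Agilent Feature Extraction 10.7.1.1; per the file headers, the processed signal is a spot intensity, background-subtracted and detrended but not normalised between arrays. The authors' value table is on the log2 scale, and each of its columns has a median of 9.43, so the arrays were brought to a common scale before it was deposited. Quantile normalization would give equal medians, but so would scaling by the median. The steps behind the table are not given in the sources used here. Within each array its values ranked spots as the processed intensity did (Spearman correlation across probes of 1), and 42475 of its 42535 entries were matched to the 42477 probes of the scanner files.

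The main setting took the log2 of the processed intensity of 43734 non-control spots, left out the 32 to 108 spots per array marked as outliers (0 spots were saturated), averaged the spots of a probe, and subtracted each array's 75th percentile. The SD between replicate spots of a probe was 0.0963 to 0.166 on the log2 scale. A gene is a locus of the array's annotation, and its value is that of its probe with the highest mean signal. This gave 29695 genes, of which 27531 were well above background on at least 1 array and 22120 on all 8; 7801 have several probes. For 101 genes the chosen probe was dim while another was above background. Between the probes of a gene the SD of a difference was 0.045 to 0.072 (median per comparison), and 2.02% to 11.4% of called genes with several probes had probes of opposite sign. A further 569 probes carry no locus name and were left out of the comparisons.

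A gene counted as higher or lower in a comparison of 2 arrays at a log2 difference of at least 1 with the brighter spot well above background; where the dimmer spot was not, the difference is a lower bound against the array's detection level. The 8 comparisons are iron withheld against supplied in each genotype and tissue, and fit-1 against wild type in each tissue and iron level. Shares are given with Wilson 95% intervals, which cover counting error only.

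Tests used limma 3.58.1 in R 4.3.3, lmFit and eBayes, on genes well above background on at least 2 of the 8 arrays, with Benjamini-Hochberg adjustment at 0.05. The models gave 6 contrasts. The iron effect per tissue, and its difference between tissues, used each genotype and tissue as a block. The genotype effect per tissue used each iron level and tissue as a block. The difference of the iron effect between genotypes, over both tissues, again used each genotype and tissue as a block. Each leaves 2 residual degrees of freedom, to which the prior adds 1.50 to 1.70. Both tissues are fitted together, so the effects of a gene in roots and in shoots share the same error. Tested on simulated data, the iron contrast in roots recovered 2%, 14%, 74% and 92% of genes planted at log2 effects of 1, 2, 3 and 4, with 7 false calls, and the size rule recovered 54%, 98%, 98% and 100% with 2044 false calls among 26755 genes. The spread in this simulation was assumed, not measured, and the size rule was applied without its condition on background. Real comparisons such as wild-type shoots gave fewer calls in all (167 and 373), so these false calls do not estimate those in the data.

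Before the data were examined, 27 gene lists were fixed, 16 by gene (134 members) and 11 by words in the array's gene descriptions, as were the comparisons, the tests and all alternatives except the one marked as added. Of the 134 members 128 were used. OsFIT, OsHRZ1 and OsbHLH133 are not on the array, and OsCRD1, OsDVR and ENA2 were left out because the array describes their loci as other genes. A list's median over its measured members, with lower bounds taken at their bound, was set against 10000 random lists of equal size matched on mean signal in 20 bins, and given as a percentile; genes of a list are not independent. Lists with fewer than 3 measured members in a comparison were left out there. A markers list of seed storage proteins and alpha-amylases was added after the largest differences had been seen.

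Named genes follow a rule fixed at the same time: OsFIT first, then members of the fixed lists, and for each comparison up to 8 genes in each direction with the largest difference among those past the size rule whose probes all went in 1 direction, passing over genes with no product name (2 to 11 per direction); for limma, up to 8 genes per direction with the smallest adjusted p. The text describes some of these. Descriptions of gene products are those of the array or textbook knowledge.

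The alternatives were quantile normalization between the arrays, scaling by the median, normexp background correction with an offset of 50, the authors' table, the mean over probes, outlier spots left in, both spots above background, thresholds of 1.5-fold and 3-fold, for limma no filter on dim probes, a filter on all 8 arrays, a trended and robust prior and leaving out each array pair in turn, and for lists random lists without matching. Counts without 129 genes that the closing observations doubt were added after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and version 1.17.8 of data.table. The arrays lie on 3 slides: all root arrays on one, wild-type shoots on another and fit-1 shoots on the last.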

Results

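The data are transcript levels in roots and shoots of rice seedlings (Oryza sativa, cultivar Nipponbare) of wild type and of fit-1, a line named after OsFIT, a basic helix-loop-helix regulator of iron uptake. OsFIT (Os04g0381700) has no probe on this array, so the gene that the line is named after was not measured and the genotype labels could not be checked on it. Seedlings 14 days old had spent their last 5 days in nutrient solution with 0.1 mM Fe(III)-EDTA or without iron. Genotype, tissue and iron supply make 8 groups, each measured on 1 one-colour Agilent array that carried a pool of 3 biological replicates. There are no replicate arrays, so the comparisons between single arrays below have no error between plants and no test, and "higher" and "lower" there mean at least 2-fold apart with the brighter spot well above background. The number of arrays limits the precision. Between 81.3% and 86.3% of spots per array were well above background, and the 75th percentile of signal ranged from 1941 to 3648. The correlation of log2 signals was 0.954 to 0.984 between root arrays and 0.980 to 0.995 between shoot arrays. It was taken across probes well above background on all 8 arrays, which leaves out dim probes, and probes are not independent replicates. Values are log2 signals relative to each array's 75th percentile, and genes are given with their locus identifiers, which carry the chromosome number; no genome coordinates were used.

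The comparison of wild-type roots without and with iron asks which transcripts respond to iron shortage. The machinery that grasses use to take up iron with secreted phytosiderophores was higher: 11 of the 11 genes of the strategy II list were higher without iron, with a median log2 difference of 4.47. OsIRO2 (Os01g0952800), a transcription factor of iron acquisition, was higher by 5.73, OsYSL15 (Os02g0650300), the transporter for iron-phytosiderophore complexes, by 5.32, and OsNAAT1, nicotianamine aminotransferase, by 4.60. TOM1 (Os11g0134900), which exports deoxymugineic acid, was higher by 4.47 and OsNAS1 (Os03g0307300), a nicotianamine synthase, by 4.13. The methionine cycle, which supplies the precursor of these compounds, had 8 of 12 genes higher and a median of 1.60, with OsDEP (Os11g0484000) at 2.81 and OsIDI4 (Os09g0453800) at 2.32.

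Iron storage went the other way in wild-type roots. OsVIT2 (Os09g0396900), a vacuolar iron transporter, was lower by a log2 difference of -4.53, and the ferritin genes OsFER1 (Os11g0106700) and OsFER2 (Os12g0106000) stood at -1.93 and -1.68, while OsVIT1 (Os04g0463400) was at -0.21. The iron regulators were split: OsIMA1 (Os01g0647200), which encodes a short iron-responsive peptide, was higher by 4.40 and OsIRO3 (Os03g0379300) by 3.59, whereas 7 of the 9 measured members were less than 2-fold apart. Among the transporters that move iron within the plant, 4 of 8 measured genes were higher, among them OsOPT7 (Os03g0751100) at 3.70 and OsYSL16 (Os04g0542800) at 1.92. Sulfate uptake followed, with OsSULTR1;2 (Os03g0196000) at 2.82 and a list median of 1.05 over 4 genes.

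Defence genes were much lower without iron in wild-type roots: 10 of 11 members of the list of defence and diterpenoid phytoalexin genes were lower, with a median of -3.83. These included the momilactone and phytocassane biosynthesis genes CYP99A2 (Os04g0180400) at -5.13, OsKSL4 (Os04g0179700) at -5.06, OsKSL7 (Os02g0570400) at -4.91 and OsCPS2 (Os02g0571100) at -4.89. Germin-like proteins were lower in 10 of 16 measured genes and higher in 0 (median -1.52). WRKY factors were lower in 13 of 66 and higher in 2 (median -0.30), and glutathione S-transferases in 12 and 1 of 53 (median -0.28). In fit-1 roots 5 of 70 WRKY factors were lower and 4 higher (median -0.02). The zinc transporters OsZIP5 (Os05g0472700) and OsZIP9 (Os05g0472400) were at -2.81 and -1.41, while the list of zinc, manganese and copper transport had a median of 0.02, with 3 of 11 genes lower, 0 higher and 8 under 2-fold.

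Some leaf transcripts were also higher on the root arrays without iron. Of the leaf markers 4 of 6 were higher in roots of each genotype, with medians of 1.47 in wild type and 1.30 in fit-1. Of the photosystem subunits 19 of 30 were higher in wild type and 12 in fit-1 (medians 1.11 and 0.97), and of the chlorophyll-binding proteins 7 of 12 and 1 of 12 (medians 1.08 and 0.86). Chlorophyll synthesis genes were higher in 2 of 8 cases in each genotype (medians 0.57 and 0.66), with OsCHLI (Os03g0563300), a magnesium chelatase subunit, at 1.38 and 1.23. Seed storage transcripts headed the list of largest differences in wild-type roots: the prolamin genes Os05g0328800 and Os05g0329700 were both higher, the first by at least 7.21 on the log2 scale, and the glutelin gene Os02g0249900 was at least 6.27 higher. Among the genes with the largest decreases were Os02g0112900, an aminotransferase-like gene (at least -6.46), Os12g0189300 of the isocitrate lyase family (-6.16) and Os03g0860100, an ethylene response factor (-6.15).

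In all, 923 genes were higher and 1168 lower without iron in wild-type roots, of 25303 genes above background there. The 2-fold threshold alone made 2044 false calls among 26755 simulated genes. The spread between arrays was assumed there, and wild-type shoots gave fewer calls in all (167 and 373), so 2044 does not estimate the false calls here. Without replicate arrays, the share of the 923 and 1168 genes that differ by chance is not known. The medians of the strategy II, methionine cycle, leaf marker, photosystem and chlorophyll-binding lists lay at percentile 100 of random lists matched on signal, and those of the defence, germin-like, WRKY and glutathione S-transferase lists at percentile 0. With normexp background correction the counts were 465 higher and 755 lower.

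**Figure D1:**
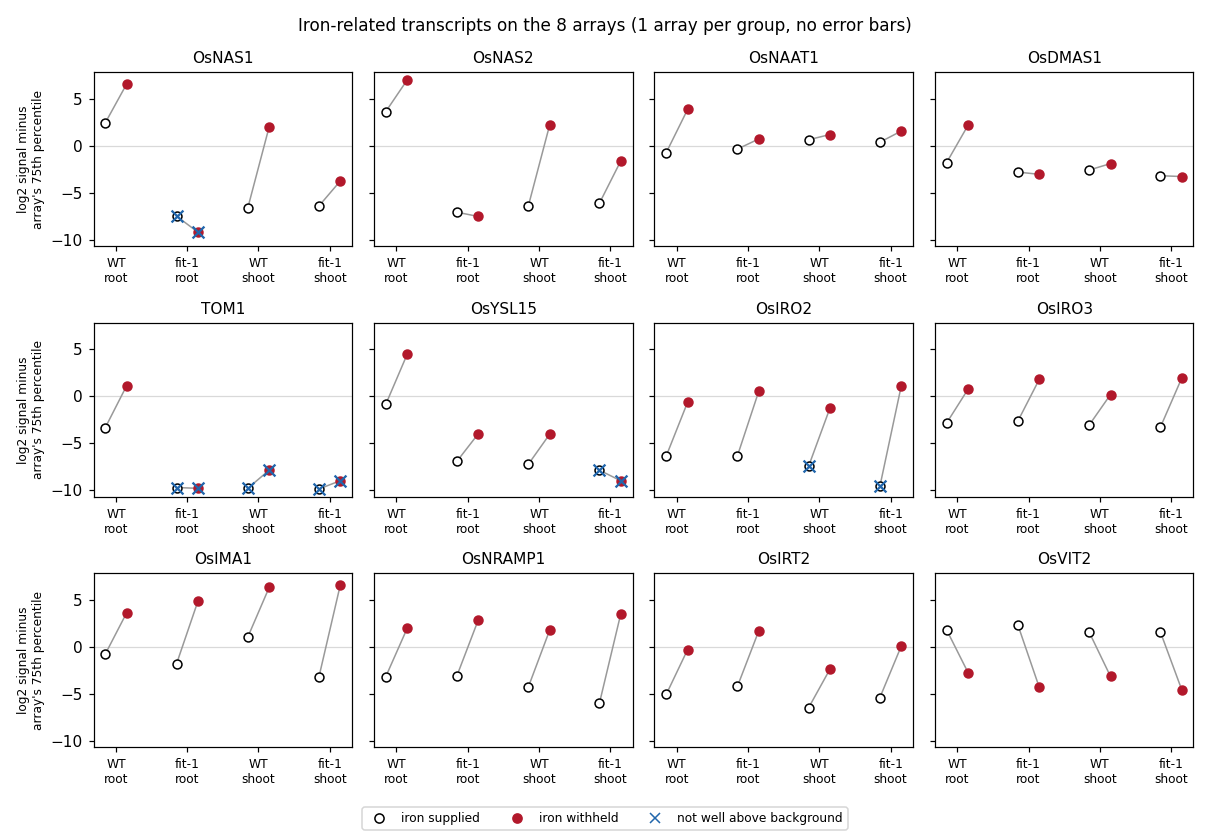
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 iron-related genes in the roots and shoots of both genotypes, with 1 array per point, iron supplied (open) and withheld (filled), no error bars, and crosses on points not well above background. OsYSL15 was 5.32 higher without iron in wild-type roots and 2.93 higher in fit-1 roots, whereas OsIRO2 was 5.73 and 6.89 higher.

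The same comparison in fit-1 roots asks which of these responses are seen in the mutant line. The strategy II list divided: OsIRO2 and 4 of the transporters were higher without iron, while of the phytosiderophore synthesis genes OsNAAT1 was higher and OsNAS2 and OsDMAS1 were not. OsIRO2 was higher by 6.89, OsNRAMP1 (Os07g0258400), a metal transporter, by 5.95 and OsIRT2 (Os03g0667300), a ferrous iron transporter, by 5.92. OsYSL15 was higher by 2.93, OsIRT1 (Os03g0667500) by 1.85 and OsNAAT1 by 1.08, whereas OsNAS2 (Os03g0307200) stood at -0.46 and OsDMAS1 (Os03g0237100), deoxymugineic acid synthase, at -0.24, and neither OsNAS1 nor TOM1 was well above background on either fit-1 root array. OsNAS2 lay just above the detection level on both arrays (log2 signals of -7.06 with iron and -7.51 without), so its difference is uncertain. The strategy II list had 6 of 9 measured members higher and a median of 1.85. The methionine cycle had 0 of 12 genes higher or lower by 2-fold, with a median of 0.05, and the sulfur list was at 0.04.

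Iron storage transcripts were lower in fit-1 roots too, with OsVIT2 at -6.64, OsFER1 at -2.85 and OsFER2 at -2.69. OsIMA1 was higher by 6.66, OsOPT7 by 5.02 and OsIRO3 by 4.44. Of the defence list, 3 of 11 genes were lower, with a median of -0.82, and OsPR1b (Os01g0382000), a pathogenesis-related gene, was at -0.03 against -2.19 in wild-type roots. Germin-like proteins had a median of -0.48, phenylalanine ammonia-lyase genes of the phenylpropanoid entry list -0.65 (-0.62 in wild-type roots), metallothioneins -0.33 (0.60 in wild-type roots) and nitrogen uptake genes -0.39 (0.43 in wild-type roots). The largest decrease among genes with a named product was that of Os04g0538400, annotated as nodulin 21, at -8.64. Leaf markers and seed storage transcripts were again among the higher genes, with the prolamin gene Os05g0328800 at least 4.69 higher.

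In fit-1 roots 709 genes were higher and 823 lower, of 25734 above background. Of the 923 genes higher in wild-type roots, 362 were also higher in fit-1 (39.2%, Wilson 95% interval 36.1 to 42.4), and the median log2 difference of the 923 in fit-1 was 0.85. Of the 1168 genes lower in wild-type roots, 387 were lower in fit-1 (33.1%, 30.5 to 35.9), with a median of -0.71. Selected the other way, 51.1% of the genes higher and 47.0% of the genes lower in fit-1 were so in wild type. These intervals cover counting error only, and with normexp background the fit-1 counts were 300 and 461.

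**Figure D2:**
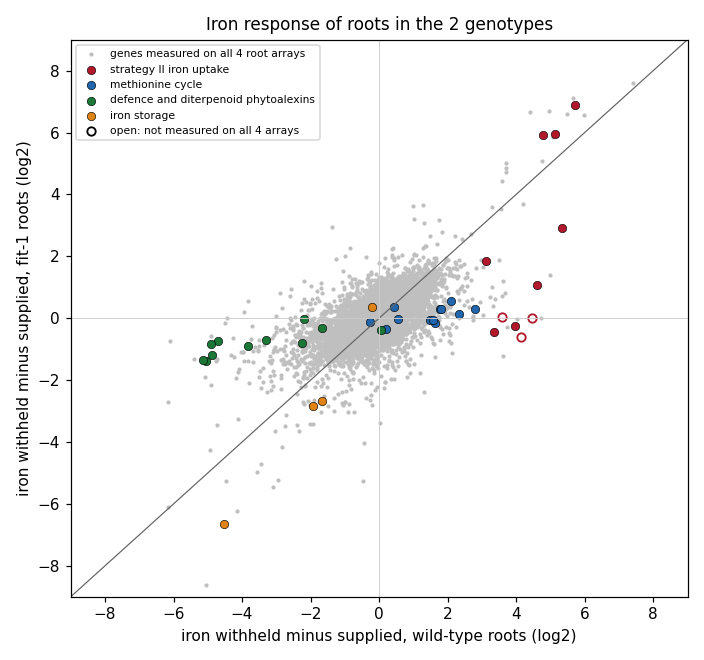
Log2 difference without minus with iron in wild-type roots (horizontal axis) and fit-1 roots (vertical axis), 1 point per gene, from 1 array per group, with 4 gene lists coloured, open circles for list genes not measured on all 4 root arrays, and the line of equal response. The methionine cycle lies at a median of 1.60 in wild type and 0.05 in fit-1, and the defence list at -3.83 and -0.82.

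Limma tested the iron effect in roots across both genotypes. The disagreement between genotypes is part of its error, which is pooled over roots and shoots. The SEs and p-values for roots therefore rest in part on the shoot arrays. Median absolute iron differences were smaller in shoots (0.095 and 0.109) than in roots (0.226 and 0.208 in wild type and fit-1), so the pooled error may understate the spread in roots. By this test iron shortage in roots raised 219 genes and lowered 65 of 26804 at an adjusted p of 0.05. Leaf genes were among them: OsRBCS5 (Os12g0291400), a Rubisco small subunit, rose by 1.53 (SE 0.0778), OsCHLI by 1.30 (SE 0.0807), Os02g0764500, annotated as Lhca5, by 1.94 (SE 0.069) and OsAPX8 (Os02g0553200), an ascorbate peroxidase, by 1.14 (SE 0.0891), each with an adjusted p of 0.0499 and higher in 2 of 2 pairs. Os04g0545000, annotated as a WRKY factor, rose by at least 1.28 in each genotype, and Os03g0679700, the thiamine synthesis gene thiC, by 1.92 (SE 0.074). Among those that fell were Os12g0189300 with an effect of -6.14 (SE 0.127), Os06g0486900, a mitochondrial formate dehydrogenase, at -1.88 or lower in each genotype, and the peroxidase gene Os07g0531400 with -4.87 (SE 0.237), all at the same adjusted p.

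By list, 9 of 30 photosystem subunits rose over all genes tested and 27 when adjusted over the list alone, and for chlorophyll-binding proteins these counts were 0 and 12 of 12. Leaf markers gave 3 over all genes and 6 of 6 adjusted over the list alone, and chlorophyll synthesis 1 and 6 of 8. The defence list (11 genes), the methionine cycle (12) and the germin-like proteins (18) gave 0 in either direction, both over all genes tested and adjusted over the list alone. Class III peroxidases gave 3 that rose and 3 that fell of 124 over all genes, and 9 and 21 adjusted over the list alone. For glutathione S-transferases the counts were 0 and 0 of 55 over all genes and 6 and 18 adjusted over the list alone, and for the antioxidant enzymes 2 and 0 of 11, and 4 and 2. Of 11 strategy II genes, 0 rose over all genes and 4 when adjusted over the list alone, and 0 and 3 of 4 iron storage genes fell. The call rests on a narrow margin: limma named 0 genes in either direction under median scaling (7278 genes at a raw p under 0.05), with the mean over probes (7083), without the filter on dim probes (6935) and when any 1 of the 4 array pairs was left out (5170 to 5796). Under normexp background the split turned to 1253 higher and 2250 lower, and with genes above background on all 8 arrays it was 1134 and 794.

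The comparison of wild-type shoots without and with iron gave fewer differences. OsNAS2 and OsNAS1 were each higher by 8.64, and the coding sequences of these paralogs are near-identical, so their probes were not taken as independent. OsIMA2 (Os07g0142100) was higher by 7.63, OsIRO2 by at least 6.20, OsNRAMP1 by 6.06 and OsFRO1 (Os04g0578600), a ferric reductase, by 5.39. OsVIT2 was at -4.72, OsFER1 at -2.88 and OsFER2 at -2.70. OsHRZ2 (Os05g0551000), a haemerythrin-domain ubiquitin ligase, was higher by 1.45.

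Of the strategy II list 6 of 10 measured genes were higher in wild-type shoots, with a median of 3.66. The methionine cycle stayed at 0.03, with 0 of 12 genes 2-fold apart, and so did chlorophyll synthesis (median 0.01, 0 of 8). Photosystem subunits, which were higher in roots, had 0 of 30 genes 2-fold apart and a median of -0.14, at percentile 0 of matched lists. The defence list had a median of 0.27, with OsPR1b higher by 2.48 and OsCPS2 by 1.33. Totals were 167 genes higher and 373 lower, of 25381 above background. Of these, 61 and 153 rest on a lower bound against a dim spot; requiring both spots above background left 106 and 220, and normexp background left 81 and 156.

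In fit-1 shoots the iron-responsive genes were again at the top, mostly with larger differences than in wild type. OsIMA1 was higher by 9.79 against 5.29 in wild-type shoots, OsNRAMP1 by 9.52 against 6.06, OsFRO1 by at least 8.08 against 5.39, and OsIRO3 by 5.24 against 3.26. OsNAS1 and OsNAS2 had smaller differences, 2.66 and 4.51 against 8.64 for each in wild type, and OsYSL15, higher by 3.21 in wild-type shoots, was not well above background on either fit-1 shoot array. OsVIT2 stood at -6.16, OsFER1 at -3.58 and OsFER2 at -3.45, and OsHRZ2 was higher by 3.22. Os05g0349800, annotated as embryonic abundant protein 1, was higher by at least 9.15, and Os03g0322900, a late embryogenesis abundant protein, by 7.21.

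The strategy II list had 6 of 8 measured genes higher in fit-1 shoots and a median of 3.58, and iron storage 3 of 4 lower with a median of -3.52. Expansins (median -0.24) and metallothioneins (median -0.25) lay at percentile 0. Totals were 375 higher and 264 lower, of 25358. Normexp background changed the split to 187 and 76, and requiring both spots above background left 157 lower.

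Across both genotypes limma named 0 genes for the iron effect in shoots, with 1386 of 26801 at a raw p under 0.05. The error of this test also holds the disagreement between genotypes in roots. The 0 therefore does not show that shoot responses disagreed between genotypes. Adjusted over the list alone, 4 strategy II genes and 4 iron regulators rose, and 1 iron regulator and 3 of 4 iron storage genes fell, against 0 of each over all genes tested. Likewise over the list alone, 3 of 9 genes for iron transport within the plant rose, and 2 of 11 zinc, manganese and copper transport genes and 1 of 124 class III peroxidases fell. The difference of the iron effect between roots and shoots gave 0 genes (4412 at a raw p under 0.05), and 1 with a trended, robust prior. Adjusted over the list alone, the difference passed for 28 of 30 photosystem subunits, 12 of 12 chlorophyll-binding proteins, 6 of 6 leaf markers and 6 of 8 chlorophyll synthesis genes, all higher in roots. It also passed for class III peroxidases (6 higher and 14 lower of 124), glutathione S-transferases (3 and 2 of 55), the antioxidant enzymes (3 and 0 of 11), phenylpropanoid entry (0 and 2 of 5) and WRKY factors (1 and 1 of 74). Of the iron regulators 1 was lower, and 1 gene each of the zinc, manganese and copper transport and sulfur lists was higher. The difference of the iron effect between genotypes over both tissues gave 0 genes of 26802 (678 at a raw p under 0.05). Adjusted over the list alone 1 gene in any list passed, OsVIT2 of the 4 iron storage genes, with an effect of -1.77 (SE 0.239). The disagreement between roots and shoots is part of the error of this test. A genotype difference present in 1 tissue only therefore fails it by construction, so the 0 does not show equal responses in roots.

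**Figure D3:**
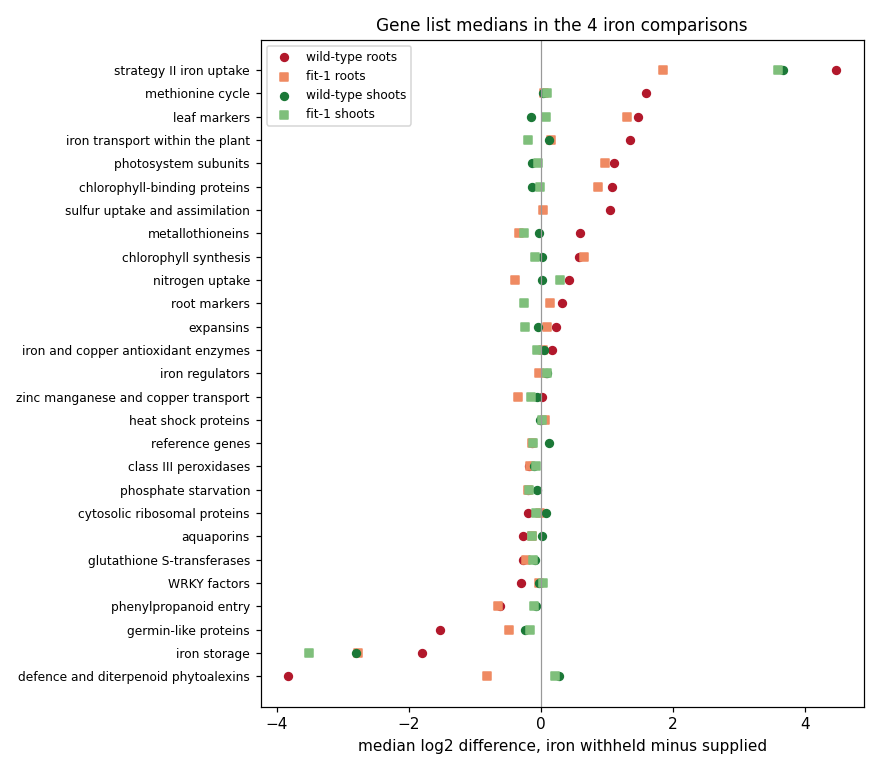
Median log2 difference without minus with iron (horizontal axis) of each gene list with at least 3 measured members, for the roots and shoots of both genotypes, from 1 array per group and without error bars. Strategy II iron uptake lies between 1.85 and 4.47, iron storage between -3.52 and -1.81, and the defence list at -3.83 in wild-type roots.

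The comparison of fit-1 with wild type in roots with iron asks what differs when iron is supplied. The nicotianamine synthase genes were far lower in fit-1: OsNAS2 was at -10.71 and OsNAS1 at -9.86 or lower, and OsYSL15 was at -6.05 and TOM1 at -4.08 or lower. The fit-1 signal of OsNAS2 lay just above the detection level with and without iron, so the sizes of its differences are uncertain. OsIRO2 was at 0.03 and OsIRT1 at -0.48, so the strategy II list, with 6 of 11 genes lower, had a median of -1.01. Of the nitrogen uptake genes 4 of 8 were higher in fit-1 and 0 lower (median 1.01), led by the ammonium transporter OsAMT1;3 (Os02g0620600) at 2.01. Metallothioneins had 7 of 15 higher and 2 lower (median 0.97), and germin-like proteins 9 of 18 higher and 1 lower (median 1.01). Without iron the nitrogen uptake list had a median of 0.07, with 0 of 7 genes higher, and metallothioneins of -0.00, with 1 of 15 higher and 1 lower. Over both iron levels limma called 0 of 7 and 0 of 15 of them, both over all genes tested and adjusted over the list alone. The disagreement between iron levels is part of that test's error, so a difference at 1 level only tends to fail it. Cytosolic ribosomal proteins had a median of -0.56 and the reference genes of -0.49, with OsGAPDH (Os04g0486600) at -0.60.

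The largest differences of genes higher in fit-1 lay outside the iron lists. Os12g0629700, a thaumatin-like gene, was at least 8.50 higher in fit-1, Os12g0230100, annotated as a Clp protease subunit, at least 8.36, and the disease resistance gene Os11g0639600 at least 7.70, while the protein kinase gene Os11g0691100 was at -8.35. Totals were 1809 higher and 1774 lower in fit-1, of 25401. Normexp background left 1007 and 937.

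Without iron, the gap in the uptake genes between fit-1 and wild-type roots was wider by list median, a change not tested in roots alone. The gaps with and without iron come from the same root arrays as the iron responses of roots, so they are not independent of them. For OsNAS1 and TOM1 both iron levels give bounds, which cannot show whether their gap widened. OsNAS1 was at -14.69 or lower, OsNAS2 at -14.52, TOM1 at -9.24 or lower, OsYSL15 at -8.44, ENA1 (Os11g0151500), a nicotianamine exporter, at -5.85, OsDMAS1 at -5.22 and OsNAAT1 at -3.13. OsIRT2 and OsIRO2 were higher in fit-1, by 2.01 and 1.19. The strategy II list had 8 of 11 genes lower and a median of -5.22, and the methionine cycle 9 of 12 lower and a median of -1.66, with OsDEP at -2.96. With iron the methionine cycle had 0 of 12 lower and a median of -0.23. Over both iron levels limma called 1 of 12 lower, both over all genes tested and adjusted over the list alone. That test is poorly placed to detect a gap that differs between iron levels, since this disagreement is part of its error. Os12g0132500, an antiporter of the same family as TOM1, was at -9.98.

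Defence genes were higher in fit-1 roots without iron, in 10 of 11 cases with a median of 3.97, against 5 of 11 and a median of 0.94 with iron. The value without iron and the iron response of wild-type roots share the 1 array of wild-type roots without iron, so they are not independent. OsCPS2 was higher by 5.77, OsKSL7 by 4.75, CYP99A2 by 4.47 and OsPR1b by 4.19. Germin-like proteins (12 higher and 1 lower of 18, median 2.18) and WRKY factors (14 and 1 of 71, median 0.36) lay at percentile 100. Zinc, manganese and copper transporters (4 higher and 2 lower of 11, median 0.80) lay at 99.98. Iron storage was at -0.94, expansins at -0.40 and class III peroxidases at -0.19. The alpha-amylase gene Os09g0457600 was at -6.86 or lower. Totals were 1844 higher and 1170 lower, of 25968, and 1080 and 598 with normexp background.

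Over both iron levels limma called 2752 genes higher and 2985 lower in fit-1 roots, of 26804. The disagreement between iron levels is part of the error of this test. That error is pooled over roots and shoots, so the SEs and p-values for roots rest in part on the shoot arrays. Of the strategy II genes 4 of 11 were lower over all genes tested and 5 when adjusted over the list alone: OsNAS2 with an effect of -12.62 (adjusted p = 0.0271), OsYSL15 with -7.24 (SE 1.32, adjusted p = 0.0440), OsNAS1 (adjusted p = 0.0415) and TOM1 (adjusted p = 0.0330), each lower in 2 of 2 pairs. OsNAS1 and TOM1 were not well above background on the fit-1 root arrays, so their fitted effects measure no size. OsNAS2 lay just above the detection level there, so the size of its effect is uncertain. CYP99A3 (Os04g0178400) and OsPR1a (Os07g0129200) of the defence list, which passed in 2 of 11 genes both over all genes tested and adjusted over the list alone, were higher by 2.94 and 1.76 (adjusted p = 0.0299 and 0.0231), and OsCATA (Os02g0115700), a catalase, by 1.66 (adjusted p = 0.0196). The transcription factor gene OsbHLH057 (Os07g0543000) was higher by 1.11 (SE 0.0766, adjusted p = 0.0150). Cytosolic ribosomal proteins were lower in 65 of 150 genes over all genes tested and in 127 when adjusted over the list alone (median effect -0.46). The reference genes were lower in 1 and 3 of 3 (median effect -0.53). Germin-like proteins were higher in 4 and 11 of 18, and lower in 2 under either adjustment. The smallest adjusted p, 0.00338, was shared by Os11g0639600, Os11g0540100, Os11g0695900 and Os12g0631800. With either root pair left out limma called 0 genes, although 9161 and 7801 had a raw p under 0.05, and with either shoot pair left out 343 higher and 82 lower. Without the filter on dim probes the counts were 1800 and 1657, and normexp background gave 4935 lower.

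In shoots, the comparison of fit-1 with wild type cannot be separated from the slide, since the wild-type shoot arrays share 1 slide and the fit-1 shoot arrays another. With iron, OsIMA1 was at -4.20 and OsNRAMP1 at -1.67 in fit-1, and without iron they were at 0.30 and 1.79. Without iron OsIRT2 was higher by 2.45, OsIRO2 by 2.34, OsIRO3 by 1.76 and OsHRZ2 by 1.58, while OsNAS1 was at -5.75, OsNAS2 at -3.79 and OsDMAS1 at -1.38. The medians of the strategy II list were -0.09 with iron and 0.01 without, over members that went both ways, and that of iron storage without iron was -0.75. OsbHLH057 was higher by 1.05 and 1.18.

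As in roots, the largest differences in shoots included genes outside the iron lists, such as Os04g0338100, annotated as IN2-2 (9.52 with iron and 9.79 without), the protein kinase gene Os02g0615800 (8.86 and 10.07) and the F-box gene Os11g0539600 (-6.71 and -5.85, both bounds). Totals were 1420 higher and 706 lower with iron, and 1540 and 549 without. Under quantile normalization the split with iron moved to 1207 and 965, and in the authors' table to 1208 and 948; both spots above background left 849 higher with iron and 1018 without, and normexp background 659 and 384 with iron and 899 and 298 without.

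Over both iron levels limma called 1061 genes higher and 415 lower in fit-1 shoots, of 26799, among them OsbHLH057 at 1.12 (SE 0.0766, adjusted p = 0.0163). None of the strategy II genes passed, whether over all genes tested (0 of 11) or adjusted over the list alone (0 of 11). As in roots, genes whose gap depended on iron tend to fail this test, and its error is pooled over roots and shoots. Os11g0639600 was higher by at least 6.68 without iron, and Os06g0271500, a transposon-like gene, by at least 7.50 with iron and 7.87 without, both with an adjusted p of 0.00406. Os11g0678200 was at -5.60 or lower with iron and -5.22 or lower without (adjusted p = 0.00533). All 3 were not well above background in 1 of the genotypes, in 2 of 2 pairs each. Quantile normalization gave 1046 higher and 697 lower, the authors' values 1049 and 686, and normexp background 1694 and 626. With either shoot pair left out limma called 0 genes (3631 and 4318 at a raw p under 0.05), and with either root pair left out 374 and 128.

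Over the 4 iron comparisons, heat shock proteins had medians between -0.02 and 0.06, phosphate starvation genes between -0.19 and -0.06, aquaporins between -0.26 and 0.02, the antioxidant enzymes that carry iron or copper between -0.05 and 0.16, and the reference genes between -0.14 and 0.12. Root markers were at 0.32 in wild-type and 0.14 in fit-1 roots. In wild-type roots expansins were higher in 12 of 40 genes (median 0.24, percentile 99.99), and class III peroxidases were higher in 14 and lower in 19 of 116 (median -0.18, percentile 0.04). Cytosolic ribosomal proteins had 0 of 149 genes 2-fold apart there (median -0.20, percentile 0). Their median was -0.005 in fit-1 roots (percentile 82.32), 0.08 in wild-type shoots (percentile 100) and -0.07 in fit-1 shoots (percentile 0).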

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

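The tests of the leaf transcripts below were planned before their results were seen, while the list medians at which a contrast between tissues was singled out were limited to sizes of at least 0.1 after they had been seen.

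By tests adjusted over each list alone, leaf transcripts differed between roots and shoots in their response to iron. No adjustment was made over the lists, and the genes of a list rest on the same arrays, so they are not independent. In limma's test of the difference, adjusted over the list alone, 28 of 30 photosystem subunits, 12 of 12 chlorophyll-binding proteins, 6 of 6 leaf markers and 6 of 8 chlorophyll synthesis genes passed, all higher in roots, against 0 genes of any list over all genes tested (4412 genes at a raw p under 0.05). Other lists passed in part, among them class III peroxidases with 6 higher and 14 lower of 124.

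Shoot material of the make-up on the shoot arrays was argued against as the source of the whole rise in the root pools without iron, but only if signals are linear. Of shoot-specific genes outside the photosynthesis lists, 90.76% of 725 in wild type and 92.54% of 724 in fit-1 stayed below 50% of the predicted rise. That prediction used the share of shoot RNA implied by the photosynthesis genes themselves (8.998% in wild type and 6.94% in fit-1). Compression of bright leaf transcripts on the shoot arrays would inflate this share, and was not tested. The shoot-specific genes were chosen for a shoot signal at least 32 times that of roots with iron. No such condition was set for the photosynthesis genes, so shoot tissue as the whole source is not excluded. A smaller contribution, or shoot tissue of another make-up, was not tested. Scaling between arrays was argued against, for the chlorophyll-binding and photosystem lists alone, by their lowest median over both genotypes and the scalings tried, 0.81 on the log2 scale. It stays open that shoot tissue contributed in part, or that iron shortage itself may raise these transcripts in roots. The latter hypothesis was found and tested on the same data. Light on the roots was not tested.

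The defence and diterpenoid phytoalexin list had a median of -3.83 in wild-type roots and -0.82 in fit-1 roots without iron, while both shoot pairs had positive medians, 0.27 and 0.21; this difference between tissues was not tested for the list as a whole. Gene by gene, limma's test of the difference passed for 0 of its 11 genes, both over all genes tested (4412 genes of any kind at a raw p under 0.05) and adjusted over the list alone.

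Of the 569 probes that carry no locus name, which no comparison used, 261 were well above background in wild-type roots, and of these 2 were at least 2-fold higher and 13 at least 2-fold lower without iron.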

How the results depend on the processing

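The counts without 129 doubted genes (seed and photosynthesis genes, and those 16-fold apart between the genotypes) are a test chosen only after the results were seen; the other alternatives were fixed in advance. The 16 counts of genes 2-fold apart stayed within 1.5 times under quantile normalization, median scaling, the authors' table, the mean over probes, with outlier spots left in and without the doubted genes, which gave 869 higher and 1166 lower in wild-type roots. Pairs of counts below are genes higher and then lower, in the order wild-type roots, fit-1 roots, wild-type shoots and fit-1 shoots for iron, then fit-1 against wild type in roots with and without iron and in shoots with and without iron.

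Normexp background correction gave 465 and 755, 300 and 461, 81 and 156, and 187 and 76 for iron, then 1007 and 937, 1080 and 598, 659 and 384, and 899 and 298 between genotypes. The cause was not tested. A threshold of 1.5-fold gave 2110 and 2545, 2038 and 1951, 552 and 918, and 764 and 1034, then 3582 and 4103, 3589 and 3290, 2767 and 1484, and 2717 and 1474. A threshold of 3-fold gave 326 and 528, 171 and 287, 73 and 177, and 184 and 68, then 861 and 394, 913 and 359, 764 and 344, and 883 and 226. Both changes follow from the threshold itself. Requiring both spots above background, which removes differences against a dim spot, left 106 and 220 for wild-type shoots, 157 lower for fit-1 shoots, and 849 and 1018 higher in fit-1 shoots with and without iron.

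The limma count for iron in roots was 378 higher and 149 lower under quantile normalization, 390 and 150 in the authors' table, 1253 and 2250 under normexp, 1134 and 794 with genes above background on all 8 arrays, and 1252 and 824 with a trended, robust prior. It was 0 and 0 under median scaling, with the mean over probes, without the filter on dim probes and with any pair left out (range 0 to 0), where the named genes' adjusted p of 0.0499 lies at the threshold. The count for genotype in roots was 1800 and 1657 without the filter and 4935 lower under normexp, and with a pair left out it ranged from 0 to 343 higher and 0 to 82 lower. The count for genotype in shoots was 1694 and 626 under normexp, 697 lower under quantile normalization and 686 lower in the authors' table, and with a pair left out it ranged from 0 to 374 and 0 to 128. Leaving out a pair leaves 1 residual degree fewer for the test. The difference of the iron effect between tissues gave 1 lower gene with the trended, robust prior. Apart from the threshold and the filters, the cause was not tested. The slide could not be added as a block: the iron and root comparisons already lie within slides, and in shoots genotype and slide coincide, so this was not run.

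Of the genes higher in wild-type roots, 36.0% were higher in fit-1 under median scaling, and of those lower 36.1% under quantile normalization and 36.0% in the authors' table; of the genes higher and lower in fit-1, 58.3% and 54.0% were so in wild type under normexp. The strategy II median kept its sign in the 4 iron comparisons and in both root genotype comparisons. Under normexp it was 3.83, 1.57, 2.17 and 2.49 for iron, and -0.90 and -3.99 between genotypes in roots with and without iron. In the authors' table it was 4.31, 2.34, 4.06 and 4.69, and -1.63 and -5.48. It was 2.33 in fit-1 roots under median scaling, 3.85 in fit-1 shoots under quantile normalization and 4.16 there with the mean over probes, and in shoots with iron between genotypes -0.17 and -0.31 under those last alternatives. The cause was not tested.

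Over all list medians and alternatives, 853 values moved by less than the spread between probes, 152 moved more and 5 changed sign: in wild-type shoots leaf markers at 0.076 under quantile normalization and 0.054 in the authors' table and chlorophyll-binding proteins at 0.018 and 0.022, and metallothioneins between genotypes in shoots with iron at -0.032 with the mean over probes. Values of named genes stayed in 964 cases and moved in 667, with 0 reversals, and of the genes named by limma 302 adjusted p stayed past the threshold and 50 did not, a tally without the runs that left a pair out. Of 210 list medians, 102 lay in the outer tails of the matched random lists and 93 in those of unmatched ones, and 13 lay on another side.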

Other observations

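The tests of blocks in the genome, of slides and of seed material below were chosen only after the results were seen. The criteria for small shares and for alpha-amylases were tightened after their values had been seen, which left more explanations open.

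Among genes outside the lists, Os01g0871600, annotated as a TGF-beta receptor family protein, was higher without iron by 6.69 on the log2 scale in fit-1 roots, 5.51 in wild-type shoots and 8.64 in fit-1 shoots. Os04g0538400, annotated as nodulin 21, a family related to vacuolar iron transporters, was at -5.05 in wild-type roots, -8.64 in fit-1 roots and -4.64 or lower in fit-1 shoots. Between genotypes, Os12g0132500, an antiporter of the family of TOM1, was at -5.25 in fit-1 against wild-type roots with iron and -9.98 without.

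Between the genotypes, 44 genes were at least 16-fold apart on all 4 array pairs, 39 higher and 5 lower in fit-1, and chromosomes 11 and 12 held 12 and 8 of them (27.3% and 18.2%, against 5.96% and 5.83% of measured genes). A difference between slides is argued against for the root pairs, which share a slide: 95 genes were 16-fold apart on both root pairs and 72 on both shoot pairs, a ratio of 131.9%. Blocks of the genome that differ between the lines may account for the set, since 31.82% of it lay within 5 measured loci of another member (95th percentile of random sets 4.55%, highest 13.64%), but the largest iron responses gave 40.91%, so clustering alone leaves this open. Sequence differences under single probes also stay open, as 0% of 6 genes had a second probe less than 2-fold apart (Wilson upper limit 39%). So does regulation through the iron response, with 0% of 5 genes lower in fit-1 that were higher without iron in wild type (upper limit 43.4%). Of the 44, 1 responded to iron in wild type at all. These counts say little, since the set required a 16-fold gap in shoots with iron too. Iron-induced genes such as OsNAS1 and OsNAS2 were dim there in wild type (log2 signals of -6.61 and -6.43), so the selection kept them out. The targeted gene as a direct cause was not tested.

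Seed storage genes were higher without iron in 22 of 28 measured cases in wild-type roots and 20 of 28 in fit-1 roots, with medians of 3.65 and 2.93. Seed material in the root pools may account for it, with 78.57% of the genes higher in wild type, but the alpha-amylases of germinating seed were higher in 3 of 6 cases in wild-type roots (median 1.18) and lower in 3 of 4 in fit-1 roots (median -3.49), so it stays open. A response of the whole plant to low iron also stays open, since few of the 32 seed storage genes on the array were measured in shoots. In wild-type shoots 0% of 8 were higher (upper limit 32.4%) and 2 were lower (median -0.02). In fit-1 shoots 0 of 9 were higher and 1 was lower (median -0.09), so neither shoot pair showed a rise.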
